A study of Homo sapiens with 107 samples.

How the data were processed

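The series measured CRISPR guide abundance in HEK293T cells, a transformed human embryonic kidney line, infected with a pooled lentiCRISPR library directed at RNA-binding proteins. A lentiCRISPR provirus carries Cas9 and a single guide RNA, so the number of reads from a guide insert in genomic DNA follows the number of cells that carry it. The 6 bulk libraries comprised 2 technical replicates at day 0, 2 technical replicates at day 7 from raft arrays 1 to 10 and 2 technical replicates at day 7 from raft arrays 11 to 20. A further 101 samples were single colonies picked from microRaft arrays at day 10, after 500 µM sodium arsenite for 1 h. A microRaft array is a dish floor of releasable microscopic elements on which colonies can be imaged and then collected one by one. Groups were taken from the sample titles and the isolation label.

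In the bulk samples, per the labels' protocols, genomic DNA was sonicated, guide-bearing fragments were captured with biotinylated RNA probes against the vector backbone, and the guide was amplified in consecutive PCRs. In the colonies, per the labels' protocols, crude lysate was amplified with barcoded primers around the guide and the products were pooled for a further PCR. MAGeCK and the genome build hg19 were named, per the submitters' processing notes, without a version or a role. The aligner or matching rule, the mismatches allowed, the size-factor method and any filter were not given in the sources used here.

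The deposited bulk table gave a normalized signal per guide and library, which is a read number divided by a library size factor, per the values. Every value lay within 0.001 of a whole multiple of a step that differed between libraries, so that 100% of the values came out whole. Totals recovered from the steps were 1035508 and 1116244 reads at day 0, 1276111 and 1176915 reads for day 7 arrays 1 to 10, and 1764425 and 1705930 reads for day 7 arrays 11 to 20. The median guide had 78 and 86 reads at day 0 and between 86 and 128 reads at day 7, and a level of 3 reads corresponded to between 3.28 and 5.56 normalized units. In the day 0 libraries the lowest value above 0 was 2 steps in replicate 1 and 4 steps in replicate 2, so the step rests on the spacing of values, and no count model was run on day 0. The deposited colony table gave whole read counts per insert sequence and colony, with no gene or guide name and no library total. Intervals and floors cover counting error only, because PCR reads without molecular identifiers are not independent molecules.

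The bulk table held 12470 guides. Of these, 11402 guides carried the names of 1142 genes, with 10 guides for 1129 genes, 9 for 12 genes and 4 for 1 gene. The other guides were named AAVS1 (267 guides), a safe-harbour locus, Zhang (711 guides in 71 sets), CTRL (80 guides in 8 sets) and fluorescent proteins (10 guides). The labels do not say what the Zhang and CTRL sets are. Gene names were used as the table gives them. Gene lists were matched to these names, so a member that the library carries under another symbol is left out of its list. Of the 1142 names, 1097 were current symbols in the RefSeq table of GRCh38.p14, 44 were found as synonyms and 1 was unmatched. No coordinates are given because no hg19 annotation was used here, and guides were not mapped to the genome.

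Guides with a mean normalized value of at least 30 over the 6 libraries were tested (12308 guides; 162 were left out). Values were transformed as log2(value + 1), and fold changes are on that scale, which understates the change of low guides. limma's trended fit was made over the 3 bulk groups, and the log2 fold change of a guide was the mean of both day 7 groups minus day 0. The value of a gene was the mean over its tested guides, for genes with at least 3. It was tested two-sided by permutation against 100000 random sets of as many guides drawn from all tested guides, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. The smallest p these draws can give is 2e-05. The same gene test was applied to the difference between the day 7 array sets. For 22 gene lists, the mean of the tested members was compared with 100000 random lists of as many tested genes, with adjustment over lists. Against control guides, the list mean was instead compared with means of about as many single control guides as its members have, drawn with replacement. That comparison counts guides and not genes. It leaves out the spread between genes and the error of the control mean, so its p-values are too small. Where lists are given with an estimated correlation, the p comes from limma's camera, which was also run with a preset correlation of 0.01. With the estimate, camera tests on the 3 residual degrees of freedom of the guide fit, which by itself raises p. For the large-subunit list the estimate was -0.00586, below the preset value, yet camera's adjusted p was 3.81e-08 with the preset and 0.0626 with the estimate. The estimated runs therefore do not show that correlation between members undoes a result.

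Groups, tests, gene lists, most alternative settings and the rule for named genes were fixed before the data were examined. The rule named the 10 lowest and up to 8 highest genes past the gene test with the same sign in both array sets, the 2 members with the largest absolute mean of each list past its test, and all library members of a core stress granule list. The result of 1 gene named by this rule is not reported here. For the array sets it named up to 3 genes each way among those past the test. For the colonies it named genes with 2 or more colonies, which was not possible because inserts carry no gene names. For the same reason the planned gene-level and stress granule list tests of the colonies were replaced by tests on insert sequences. In these, as many inserts as observed were drawn 100000 times with the day 7 bulk shares as weights, and the largest number of colonies sharing a guide was recorded (one-sided permutation test, smallest p 1e-05).

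The replicates are labelled technical, and nothing states separate cultures, so p-values from the guide fit measure the spread between these libraries only. Technical replicates differed by more than sampling noise: the median chi-square term of a guide was 2.33, 3.41 and 4.87 times that from read sampling alone at day 0, for arrays 1 to 10 and for arrays 11 to 20. They were therefore kept as separate libraries. Across guides, which are not independent replicates, Pearson's r between technical replicates was 0.811, 0.876 and 0.880 on the log2 scale.

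The tests were run on simulated data with guide noise, drift between time points and known changes. With 1142 genes in the simulated day 7 against day 0 comparison, the gene test called 100% of genes lowered by 1.5 and by 1 on the log2 scale, 20.8% of genes lowered by 0.5, 100% of genes raised by 0.5 and 0.838% of unchanged genes. The guide test called 5.53% of unchanged guides in the same simulation, since drift between time points is not part of the spread between technical replicates. All guides of a simulated gene had the same change. In the data, the SD over guides of the 10 lowest genes ran from 0.715 (RRM1) to 1.67 (RPL9). These rates therefore do not carry over to the data.

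Alternatives covered the pseudocount, the filter on low guides, another scaling, each library left out, the technical replicate number as a block, the median over guides, other null sets, robust rank aggregation, camera, each array set alone and a higher minimum number of guides. edgeR's quasi-likelihood test and DESeq2 were run on the reads recovered from the 4 day 7 libraries, for the comparison of array sets only. Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Of the 101 colonies, 40 had no insert in the table used here and were not analysed here.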

Results

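Guide abundance was measured by sequencing in 6 bulk libraries and in single colonies of HEK293T cells carrying a pooled CRISPR library against RNA-binding proteins. The bulk libraries comprised 2 technical replicates at day 0 and 2 technical replicates at day 7 for each of 2 sets of raft arrays, with between 1035508 and 1764425 recovered reads per library. The colonies came from imaged microRaft arrays at day 10, after 1 h of 500 µM sodium arsenite, a stressor that induces stress granules. Inserts were listed for 61 colonies, with 3421351 reads in all, and 40 further colonies were not analysed here.

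Control guides lay above guides of genes in their change from day 0 to day 7. The 267 guides against AAVS1, a safe-harbour locus whose disruption is tolerated, had a mean log2 fold change of 0.32 ± 0.40 (SD). The 711 Zhang guides had a mean of 0.29 ± 0.45, the 80 CTRL guides 0.24 ± 0.43 and the 10 guides named for fluorescent proteins 0.43 ± 0.38, against -0.14 ± 0.69 for the 11240 tested guides of genes. None of the other control sets differed from AAVS1 in a two-sided permutation test of guides (adjusted p = 0.395 for Zhang, 0.326 for CTRL and 0.395 for the fluorescent proteins). The library became less even, with a Gini coefficient of 0.252 and 0.236 in the day 0 libraries and between 0.325 and 0.331 in the 4 day 7 libraries.

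The comparison of day 7 with day 0 asks which knockouts were lost or gained during a week of growth. Of 1142 genes, 36 had lower and 6 had higher mean guide abundance than random guide sets. The lowest was RPL9, a protein of the large ribosomal subunit, with a mean log2 fold change of -1.51 ± 0.53 (SE over 10 guides), a fold change of 0.352 (permutation test, adjusted p = 0.0114). RPL11, a large-subunit protein, followed at -1.44 ± 0.25 with all 10 guides below 0 (permutation test, adjusted p = 0.0114). EIF4A3, the helicase core of the exon junction complex, fell by 1.36 ± 0.44, and SNRNP200, a helicase of the U5 snRNP, fell by 1.35 ± 0.42 (permutation test, adjusted p = 0.0114 for each). SNRNP200 rested in part on a guide that was 10.4 times higher in day 0 replicate 1 than in replicate 2; without it and other discordant guides the gene mean was -1.06 (permutation test, adjusted p = 0.0367).

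Among the next genes, RPL37 had a mean of -1.29 ± 0.41, RPL23 -1.20 ± 0.53 and RPL7 -1.20 ± 0.34, all proteins of the large subunit. COPB1, a coatomer subunit of vesicle transport, fell by 1.24 ± 0.33, SF3B3, a component of the U2 snRNP, by 1.23 ± 0.27, and RRM1, the large subunit of ribonucleotide reductase, by 1.19 ± 0.24. The permutation test gave these 6 genes adjusted p-values of 0.0200 (RPL37, COPB1 and SF3B3) and 0.0241 (RPL23, RPL7 and RRM1). All 36 lower genes had negative means in both array sets, 11 of them were ribosomal proteins, and 10 of them had every tested guide below 0. With only guides of a mean of at least 100 over day 0 and day 7 kept, which drops guides because they fell, RPL9, EIF4A3, SF3B3 and RPL23 no longer passed (permutation test, adjusted p = 0.332, 0.162, 0.139 and 0.502), and COPB1, RPL7 and RRM1 kept too few guides for a test. With the median over guides, EIF4A3, SNRNP200, COPB1 and SF3B3 did not pass (permutation test, adjusted p = 0.0876, 0.0742, 0.0548 and 0.0505).

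The 6 higher genes were RBMY1D at 0.62 ± 0.18, TLR3 at 0.53 ± 0.13, DCP1B at 0.50 ± 0.14, NSUN2 at 0.48 ± 0.18, C17orf85 at 0.47 ± 0.12 and CPEB2 at 0.47 ± 0.09 (SE over 10 guides each). RBMY1D, a germline RNA-binding protein of a multi-copy family, had an adjusted p of 0.0200, and TLR3, a receptor for double-stranded RNA, 0.0278 (permutation test). DCP1B, a decapping cofactor, had an adjusted p of 0.0381 and NSUN2, an RNA cytosine methyltransferase, 0.0457, while C17orf85 and CPEB2 had 0.0490 and 0.0495 (permutation test). Relative to AAVS1 guides these genes lay between 0.15 (CPEB2 and C17orf85) and 0.30 (RBMY1D) higher. RBMY1D was the only gene of the library called higher when AAVS1 guides served as the null set. Whether the RBMY1D guides cut a target in these cells was not examined, so its value is not shown to come from a knockout. RBMY1D also passed with each library left out, whereas TLR3 was lost without day 0 replicate 1 (permutation test, adjusted p = 0.0647) and DCP1B without day 0 replicate 1 or arrays 1 to 10 replicate 2 (0.0693 and 0.0634). Leaving out a library removed the call of NSUN2 in 3 of 6 cases, of C17orf85 in 3 and of CPEB2 in 5, with the highest adjusted p at 0.104, 0.218 and 0.0835, in turn without day 0 replicate 2, without day 0 replicate 2 and without day 0 replicate 1 (permutation test). With the median over guides, TLR3, DCP1B, NSUN2, C17orf85 and CPEB2 did not pass (permutation test, adjusted p = 0.145, 0.0976, 0.328, 0.0595 and 0.228). Robust rank aggregation kept 1 of the 6 higher calls, and a guide mean of at least 100 kept 2.

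**Figure D1:**
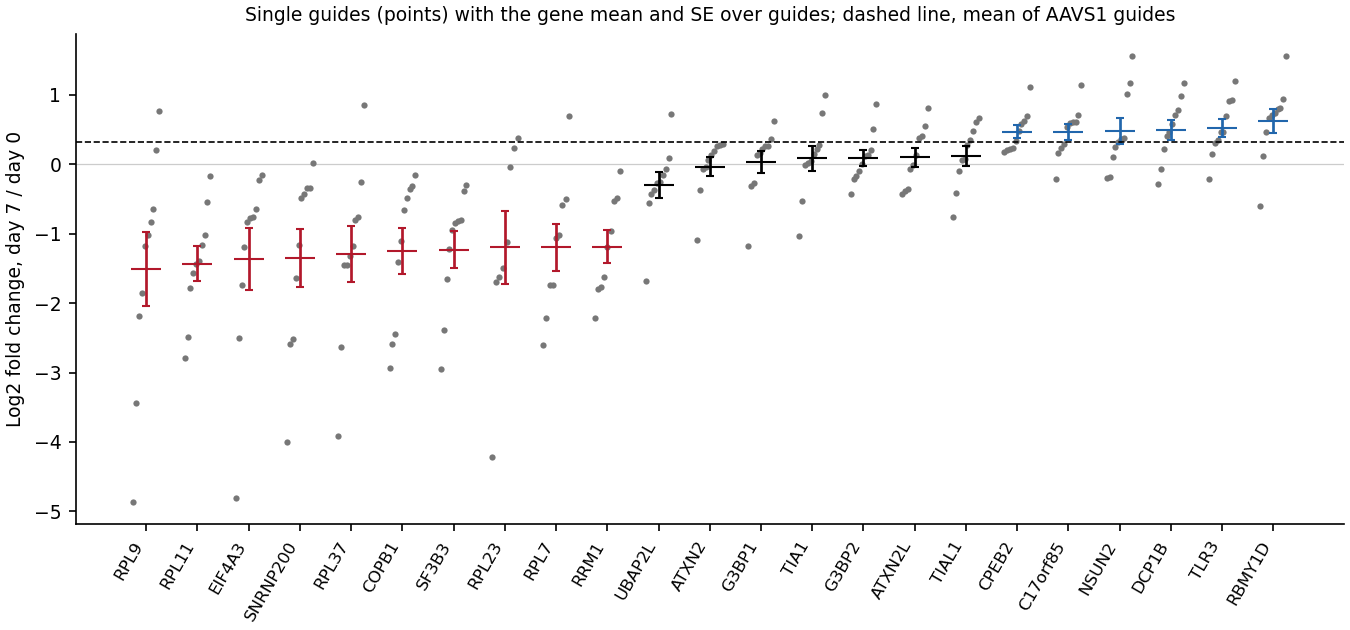
Each point is a guide, plotted by its log2 fold change from day 0 to day 7; horizontal marks with bars are gene means ± SE over guides for the 10 lowest genes (red), the core stress granule genes (black) and the 6 higher genes (blue), and the dashed line is the AAVS1 mean of 0.32. Means run from -1.51 for RPL9 to 0.62 for RBMY1D, and guides of the same gene differ widely.

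The split of calls depended on the reference. Against the AAVS1 guides, whose mean lies 0.32 above 0 on this scale, 763 genes were lower and 1 was higher. Against the Zhang guides 577 were lower and 1 was higher, and against the CTRL guides 550 were lower and 1 was higher. The lower calls against AAVS1 included 18 of the 42 genes of the germline list. They also included 26 of the 58 genes of the neuronal and tissue-restricted list. AAVS1 guides spread less than guides of genes (SD 0.40 against 0.69), and these draws leave out the error of the control mean. The counts against control guides therefore do not give the number of depleted knockouts. The 36 lower and 6 higher genes above are relative to the mean of all guides (-0.11). The number of calls was 27 without replicate 2 of arrays 1 to 10 and also 27 without replicate 2 of arrays 11 to 20, and 19 of the 36 lower genes, among them the 10 lowest, passed with each library left out in turn; camera with an estimated correlation called 0 genes.

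Camera with the preset correlation, by contrast, called 48 lower and 6 higher genes. Ribosomal and spliceosomal genes were lower as groups among the fixed gene lists. The 46 tested large-subunit ribosomal proteins had a mean log2 fold change of -0.57 ± 0.43 (SD between genes), against -0.13 for all other genes (permutation test, p = 2e-05, the smallest possible; adjusted p = 6.29e-05; adjusted p = 0.0626 with an estimated correlation). Of these, 9 were lower, 0 were higher and 37 did not pass, and 16 were lower when adjusted over the list alone. The 32 small-subunit proteins had a mean of -0.49 ± 0.29 (permutation test, adjusted p = 6.29e-05; adjusted p = 0.0777 with an estimated correlation), with 2 lower, RPS13 furthest at -1.10 ± 0.26, and 10 lower when adjusted over the list alone. With a library left out, its members called lower ran from 1 (for example without day 0 replicate 2) to 3 (without arrays 1 to 10 replicate 1). The 57 core spliceosome genes had a mean of -0.51 ± 0.35 (permutation test, adjusted p = 6.29e-05; adjusted p = 0.0626 with an estimated correlation), with 5 lower, SNRNP200 and SF3B3 furthest, and 15 lower when adjusted over the list alone.

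Genes that charge tRNAs, assemble ribosomes and initiate translation were also lower as groups. The 20 cytosolic aminoacyl-tRNA synthetases had a mean of -0.50 ± 0.25 (permutation test, adjusted p = 6.29e-05; adjusted p = 0.0777 with an estimated correlation). The glutaminyl-tRNA synthetase QARS was the 1 member past the gene test at -0.96 ± 0.25, 4 passed when adjusted over the list alone, and the valyl-tRNA synthetase VARS had -0.86 ± 0.30. QARS was lost in 4 of 6 cases when a library was left out, with adjusted p up to 0.0585 without arrays 11 to 20 replicate 2 (permutation test). The 45 ribosome biogenesis and snoRNP genes had a mean of -0.43 ± 0.26 (permutation test, adjusted p = 6.29e-05; adjusted p = 0.0777 with an estimated correlation). RRP12, a ribosome assembly factor, was lower at -1.01 ± 0.23, the only member past the gene test both over all genes and when adjusted over the list alone, and the helicase DDX18 had -0.84 ± 0.26. RRP12 was lost without arrays 1 to 10 replicate 2 and without arrays 11 to 20 replicate 2 (permutation test, adjusted p = 0.0551 and 0.0501).

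The 42 translation initiation genes had a mean of -0.34 ± 0.40 (permutation test, adjusted p = 0.00196; adjusted p = 0.114 with an estimated correlation), with 4 lower and 8 lower when adjusted over the list alone. The 4 members became 2 without day 0 replicate 2, without arrays 1 to 10 replicate 2 and without arrays 11 to 20 replicate 2. EIF6, which keeps ribosomal subunits apart and takes part in subunit assembly, fell by 1.17 ± 0.40, and EIF3C, a subunit of the eIF3 complex, by 1.06 ± 0.22. EIF3C has a near-identical copy, EIF3CL, and guide sequences were not used here, so its value can include cutting at both. The 25 genes of mRNA 3-prime end processing had a mean of -0.32 ± 0.27 (permutation test, adjusted p = 0.0366; adjusted p = 0.117 with an estimated correlation), although 0 members passed the gene test or passed when adjusted over the list alone; INTS9, an Integrator subunit, had -0.89 ± 0.26 and CPSF1, of the cleavage and polyadenylation factor, -0.78 ± 0.25. That list did not pass with the median over guides, with a minimum guide mean of 100, or with arrays 1 to 10 alone.

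The lists of germline and of neuronal and tissue-restricted RNA-binding proteins lay, in their means, above the average gene and below the AAVS1 guides. Whether the guides of each member produced a knockout was not examined. The 42 germline genes had a mean of 0.09 ± 0.21 (permutation test, adjusted p = 6.29e-05; adjusted p = 0.0777 with an estimated correlation), which was -0.23 relative to AAVS1. CPEB2, a cytoplasmic polyadenylation element binding protein, was the 1 member called higher, 0 were called when adjusted over the list alone, and DND1, a germ cell factor, had 0.43 ± 0.15. The 58 neuronal and tissue-restricted genes had a mean of 0.09 ± 0.19 and -0.23 relative to AAVS1 (permutation test, adjusted p = 6.29e-05; adjusted p = 0.0777 with an estimated correlation). TLR3, an innate immune receptor and no neuronal factor, was the 1 member called higher, also when adjusted over the list alone, and KHDRBS3, a splicing regulator, had 0.50 ± 0.14.

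The 31 deadenylation and decapping genes had a mean of 0.08 ± 0.19, which was -0.24 relative to AAVS1 (permutation test, adjusted p = 0.000165; adjusted p = 0.0895 with an estimated correlation). DCP1B was the 1 member called higher, also when adjusted over the list alone, and ZFP36L1, which recruits deadenylases to AU-rich elements, had 0.43 ± 0.14. Against AAVS1 or CTRL guides the means of these 3 lists were lower, not higher.

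Neither list of stress granule genes, whose products form the granules that arsenite induces, passed its test against random gene lists. The 54 stress granule proteins had a mean of -0.04 ± 0.29 (permutation test, adjusted p = 0.0556), with EIF4A1 the 1 member past the gene test, a gene also in the initiation list and named after its value was seen, at -0.96 ± 0.16; 0 passed when adjusted over the list alone. EIF4A1 was lost without day 0 replicate 2, without arrays 1 to 10 replicate 2 and without arrays 11 to 20 replicate 2. This list lay close to the threshold, and it passed as higher than random lists without day 0 replicate 2, without arrays 1 to 10 replicate 2 and without arrays 11 to 20 replicate 2 (permutation test, adjusted p = 0.0448, 0.0485 and 0.0365), while it was lower against CTRL guides (-0.28, adjusted p = 2.10e-05) and against AAVS1 guides (-0.36, adjusted p = 2.00e-05), both by permutation. The 7 core assembly factors in the library had a mean of 0.02 ± 0.15 (permutation test, adjusted p = 0.314), and 0 of them passed the gene test or passed when adjusted over the list alone. This list was also lower against CTRL guides (-0.22, adjusted p = 4.00e-05) and against AAVS1 guides (-0.30, adjusted p = 2.00e-05), both by permutation. These draws took single control guides and not genes, and all 22 lists were lower against either set. Neither result sets the stress granule lists apart. G3BP1 had 0.03 ± 0.16, its paralog G3BP2 0.09 ± 0.12, TIA1 0.09 ± 0.18, TIAL1 0.13 ± 0.14, ATXN2 -0.03 ± 0.13, ATXN2L 0.10 ± 0.14 and UBAP2L -0.30 ± 0.19 (SE over 10 guides each). Against AAVS1 guides, UBAP2L, ATXN2 and G3BP1 were lower, by -0.62, -0.35 and -0.29 (permutation test, adjusted p = 6.26e-05, 0.0121 and 0.0390), as were 763 of all 1142 genes, so these 3 calls do not set stress granule genes apart.

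The other lists did not pass. Their means were -0.31 for the 21 mRNA export and cap binding genes (permutation test, adjusted p = 0.0841), -0.24 for 9 elongation and termination genes, -0.20 for 5 signal recognition particle genes, -0.18 for 29 SR proteins and splicing regulators and -0.18 for 13 RNA exosome genes. They were -0.16 for 24 hnRNP genes, -0.09 for 84 mitochondrial ribosome and RNA genes, -0.08 for 16 exon junction and nonsense-mediated decay genes, -0.05 for 10 m6A genes and -0.00 for 14 microRNA pathway genes. Members were matched by name, and 21 of the 26 listed names of the export and cap binding list were tested. Its mean and counts cover only those names. Adjusted permutation p-values of these other lists lay between 0.0841 and 0.819. Within them, the SR protein list had 3 members called lower (4 when adjusted over the list alone; 1 without day 0 replicate 2, without arrays 1 to 10 replicate 2 or without arrays 11 to 20 replicate 2), and the export and exon junction lists had 1 each, also when adjusted over the list alone; the export list had 0 without day 0 replicate 2 and without arrays 11 to 20 replicate 2. The hnRNP and elongation lists had 0 over all genes, and 3 lower with 1 higher and 1 lower when adjusted over the list alone.

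**Figure D2:**
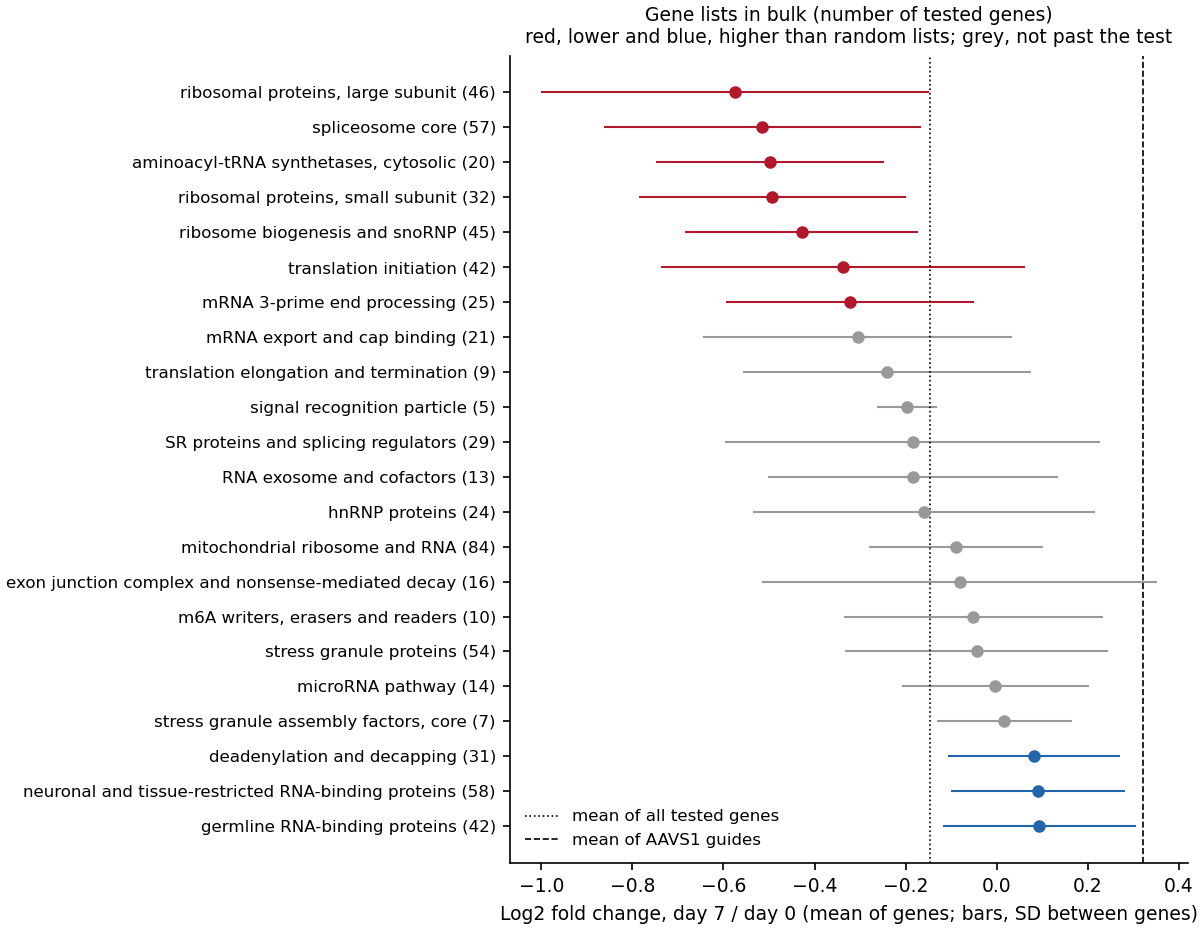
Points are the mean log2 fold change of the tested genes of each list from day 0 to day 7 and bars are the SD between genes; the dotted line is the mean of all genes and the dashed line the AAVS1 mean of 0.32. The 7 lower lists (red) have means between -0.57 and -0.32, and the 3 lists above random lists (blue) lie at 0.08 and 0.09, still below AAVS1.

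Single guides moved in both directions. With limma, 1863 guides were lower and 1840 were higher at day 7 (adjusted p at or below 0.05), among 12308. Keeping only guides with a mean of at least 100, which drops guides because they fell, gave 859 lower and 1793 higher among 9264. Of the 267 AAVS1 guides, 2 were lower and 102 higher (38.2%), against 1845 lower (16.4%) and 1491 higher (13.3%) among guides of genes. Higher calls made up 30.8% of Zhang and 28.75% of CTRL guides. The near-even split over all guides therefore does not mean that as many knockouts were gained as lost. Averaging the technical replicates first left 269 lower and 324 higher guides, and treating the day 7 libraries as 1 group of 4 left 1205 and 1226; without day 0 replicate 1 the split was 618 lower and 988 higher, and without day 0 replicate 2 it was 639 and 1017.

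Lower genes were in part shared between the array sets. Set against day 0 alone, arrays 1 to 10 had 23 lower and 4 higher genes and arrays 11 to 20 had 23 lower and 2 higher genes. RPL9 had a mean of -1.19 in arrays 1 to 10 and -1.82 in arrays 11 to 20, and RPL11 had -1.41 and -1.46. The sets shared 14 of their lower genes, where independent lists would share 0.463. Over genes, which are not independent replicates, the fold changes of both sets had r = 0.898 and a covariance of 0.119, against 0.384 and 0.00378 in simulated data without effects. With a different day 0 replicate for each set, r was 0.848 and 0.846 and the covariance was 0.116 and 0.116. Part of the excess of shared calls over independent lists can come from the shared day 0 libraries. In 20 simulated runs without effects, the highest number of shared lower genes was 0. Those runs hold no true changes, so they do not show how many calls of changed genes the shared libraries add.

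**Figure D3:**
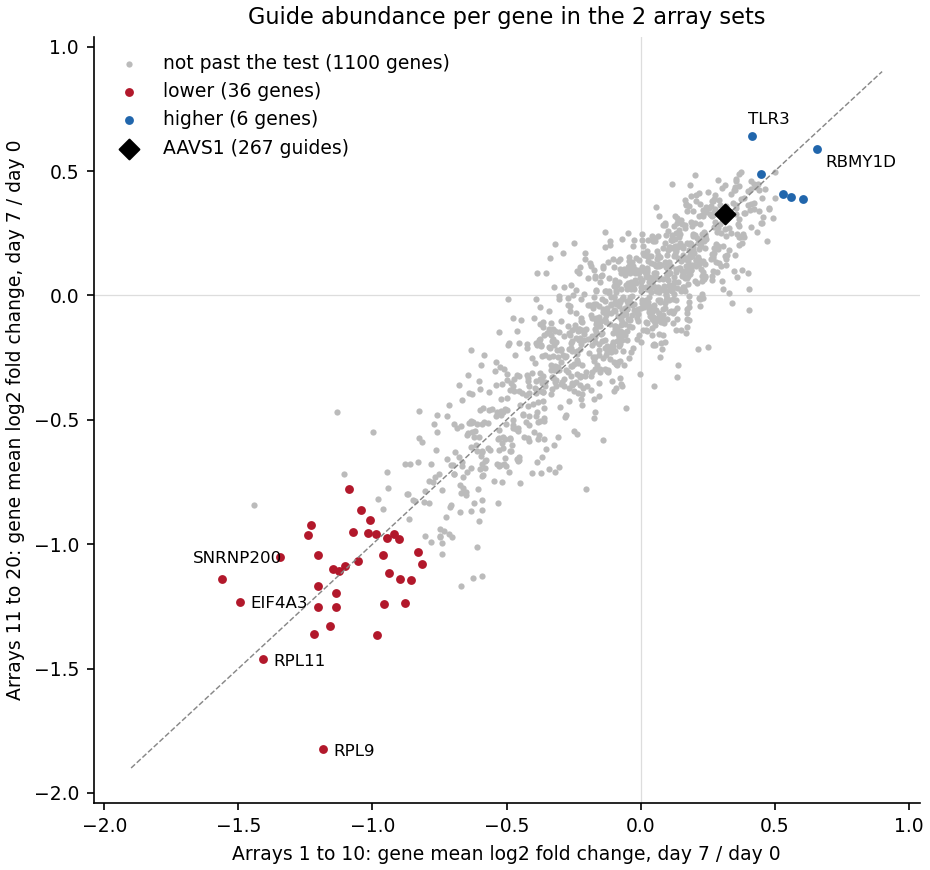
Each point is a gene, plotted by its mean log2 fold change from day 0 to day 7 in arrays 1 to 10 (horizontal) and arrays 11 to 20 (vertical); red and blue points are the 36 lower and 6 higher genes, the diamond is AAVS1, and the dashed line marks equal values. Lower genes lie below 0 on both axes, and RPL9 lies furthest below the line among them.

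A direct comparison of the array sets asks whether the separately sampled cells differed at day 7. The sets also differed in the lane number of their column names and in depth, which cannot be separated from the cells. No gene differed between the sets in the permutation test (0 of 1142; at an unadjusted p under 0.05, 27 were lower and 36 higher in arrays 11 to 20), and the same test on edgeR or DESeq2 log2 differences of the recovered reads also called 0. The largest differences, named after their values were seen, were RBM39, a splicing factor, at 0.66 ± 0.36 and RPL9 at -0.64 ± 0.29 (permutation test, adjusted p = 0.171 for each). RPL9 passed when replicate 2 of arrays 11 to 20 was left out, the 1 such call. Of single guides, 153 were lower and 164 higher in arrays 11 to 20 with limma, against 250 in all with edgeR and 59 with DESeq2 on recovered reads. The split turned on single libraries: it was 45 lower and 130 higher without arrays 1 to 10 replicate 1, 48 and 102 without arrays 1 to 10 replicate 2, 39 and 7 without arrays 11 to 20 replicate 1, and 57 and 13 without arrays 11 to 20 replicate 2.

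The colonies were collected one by one after arsenite to identify the knockout each carried. Of the 61 colonies with an insert, 27 had 1 listed insert (44.3%, 95% Wilson interval 32.5 to 56.7%), 27 had 2, 4 had 3 and 3 had 4. No listed insert took less than 17.3% of the listed reads of its colony. A cutoff not stated in the labels may have removed minor inserts, so colonies with 1 listed insert may have carried more. In the 34 colonies with 2 or more inserts, the most abundant insert took a median of 57.5% of the listed reads. Reads per colony ran from 4562 to 441968, with a median of 28993. Inserts were listed for 42 of 61 colonies from arrays 1 to 10 and for 19 of 40 colonies from later arrays (two-sided Fisher's exact test, p = 0.0389). That test counts colonies as independent although they are nested in 19 arrays, so its p does not establish a difference between the array sets.

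The same insert recurred between colonies. Of 94 distinct inserts, 87 were found in 1 colony, 6 in 2 colonies and 1, TAGTCGAGAGAAACAAGCG, in 6 colonies on 5 arrays. That insert was the most abundant of its colony in 5 of the 6 and the only insert in 2 of them, with between 7148 and 29026 reads. Among 100000 draws of 105 inserts by day 7 bulk share, the most colonies sharing a guide was 1.44 on average and 4 at most (one-sided permutation test, p = 1e-05, the smallest possible), and 0.570 guides were repeated on average against 7 observed. Counting the same insert on the same index once left 4 repeated inserts and at most 4 colonies, and counting it once per library pool left 5 and 5. With day 0 bulk shares as weights, the draws reached up to 9 colonies (permutation test, p = 0.00239). Within arrays 1 to 10 no insert exceeded 2 colonies (permutation test, p = 0.251), while within arrays 11 to 20 the most was 4 (permutation test, p = 1e-05). Inserts recurred in both: 5 were repeated in arrays 1 to 10, against 0.286 drawn on average (permutation test, p = 1e-05). In arrays 11 to 20, 2 were repeated, against 0.0498 drawn (permutation test, p = 0.00110). The draws took single inserts and ignored which inserts lay in the same colony. Inserts of a colony can recur together: the 6 inserts found in 2 colonies each fell in 5 pairs of colonies. Repeated inserts are therefore not all separate events, and p-values for their number can be too small. Which gene the insert found in 6 colonies targets was not analysed here, because inserts were not matched to guide names. No unselected colonies were used for comparison.

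**Figure D4:**
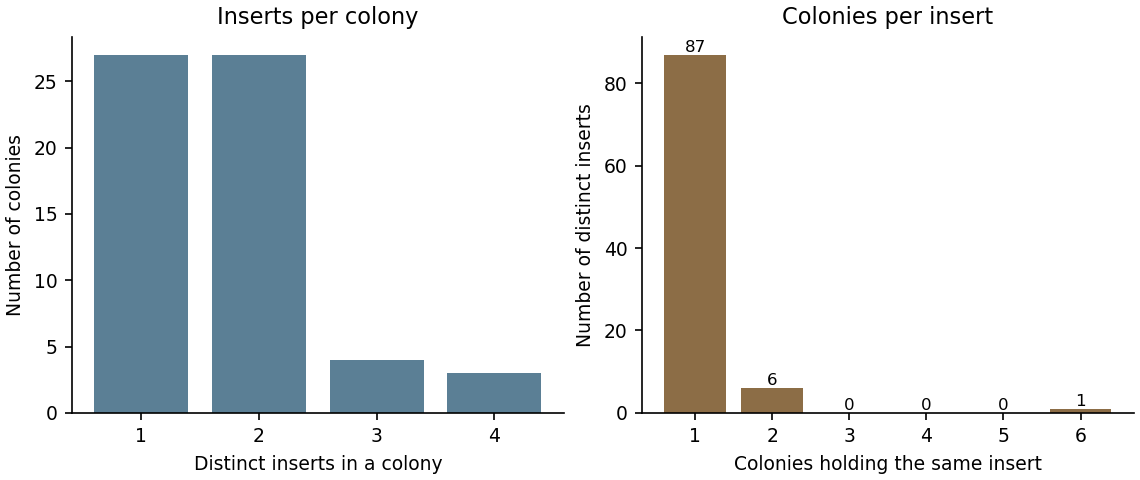
The left bars give the number of the 61 colonies (vertical) by how many distinct inserts were listed for each (horizontal). The right bars give the number of the 94 distinct inserts by how many colonies held them. Colonies with 1 and with 2 inserts number 27 each, and 87 inserts were seen in 1 colony, 6 in 2 and 1 in 6.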

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

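The guide-level comparison of array sets was chosen after the data were seen, and the prediction for its test was written before that test was run. With limma, 317 guides differed between arrays 11 to 20 and arrays 1 to 10 at day 7, while 0 genes differed in the permutation test. Both groups were sampled on the same day, and the labels give no treatment for either. The deposited column names give the libraries of arrays 11 to 20 another lane number than all others, and their depth was higher. A difference between the cells cannot be told apart from these. Drift of single guides unrelated to their target gene may account for the 317 guides. If so, guides of the same gene would not move together: the SD of the gene means of the set difference was 0.165, against 0.161 when guides were shuffled over genes and an upper bound of 0.168 for the central 95% of shuffles (permutation test, 10000 shuffles, p = 0.162). By comparison, the SD of the gene means of the day 7 against day 0 change was 0.355, against 0.220 with shuffled guides. What causes the drift stays open, and a gene effect below the resolution of this test is not excluded.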

How the results depend on the processing

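Alternatives using AAVS1 or Zhang guides as the null set, an estimated correlation, more random sets, the discordant day 0 guides left out, edgeR and DESeq2 on day 7 reads, and the index and library pool counts of colonies were chosen after seeing the data. edgeR and DESeq2 against day 0 were not run because whole reads were not accepted for the day 0 libraries, and the gene and stress granule list tests of colonies were not run because inserts carry no gene names.

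The 42 changed genes became 20 with a guide mean of at least 100, of which 7 lower and 2 higher genes were among the 42 (the filter itself removes depleted guides), 27 with arrays 1 to 10 alone, 25 with arrays 11 to 20 alone, 551 against CTRL guides, 764 against AAVS1 guides, 578 against Zhang guides and 0 with camera and an estimated correlation. With each library left out the count ran from 27 to 42. Repeating the random draws with 10 other seeds gave 30 to 40 lower and 3 to 7 higher genes, and 10 times as many random sets gave 39 and 7, so genes near the threshold are not settled by the draws. The total stayed within 1.5 times in the other alternatives, but the 6 higher genes became 2 with the median over guides and 2 with robust rank aggregation, with 1 of the 6 kept in each, 3 with at least 5 guides and 3 without the discordant day 0 guides. Of the 22 genes past the test that the rule named, 3 passed under all 20 settings with values for single genes, 2 more passed in the 19 that gave them a value, and none reversed.

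The 3703 changed guides became 593 with technical replicates averaged first, where residual freedom is lowest, and 2431 with day 7 as 1 group; with each library left out they ran from 1606 to 3445, the lone library being assumed to vary like the other groups. The 317 guides differing between array sets became 59 with DESeq2, and 46 to 238 with each library left out. Genes differing between array sets numbered 0 throughout, except 1 without replicate 2 of arrays 11 to 20 (0 to 1 over the libraries left out).

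The 10 lists past the test became 22 against CTRL or AAVS1 guides, all lower, and 0 with an estimated correlation. The estimated run rests on few residual degrees of freedom, and with the preset correlation camera passed 10 lists. Against CTRL guides the direction reversed for deadenylation and decapping (-0.15), germline (-0.14) and neuronal and tissue-restricted genes (-0.15); against AAVS1 guides they had -0.24, -0.23 and -0.23, by the construction of the null. The list of stress granule proteins, not past the test (adjusted p = 0.0556), passed as higher in 4 settings, among them arrays 1 to 10 alone (adjusted p = 0.0422, permutation test), and as lower against CTRL (-0.28) and AAVS1 guides (-0.36). The most colonies sharing an insert was 2 in arrays 1 to 10, where 5 inserts were repeated.

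With the technical replicate number as a replicate block, 3885 guides passed and 566 guides differed between array sets. The 42 genes, 10 lists and 0 genes between array sets could not change, because the block leaves the mean fold changes as they are. The deviations of same-numbered libraries correlated at -0.00261, 0.0168 and 0.00808, so the numbers do not pair the samples. Except where stated, the cause of a change was not tested. Depth limits guides with few reads, since 3 reads already correspond to 5.56 normalized units at day 0.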

Other observations

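The tests of gene symbol families, ribosomal paralogs and repeated inserts below were chosen only after the values had been seen. Grouping genes by the letters of their symbol gave 43 families, of which 8 passed a two-sided permutation test against random gene lists. Besides ribosomal and splicing families, the library held housekeeping genes outside RNA biology. The 4 CCT genes, subunits of the cytosolic chaperonin, had a mean log2 fold change of -0.70 (permutation test, adjusted p = 0.0313), and the 10 PSM genes, subunits of the proteasome, had -0.55 (adjusted p = 0.0112). The 13 PRPF pre-mRNA processing factors had -0.44 and the 53 EIF genes -0.28 (permutation test, adjusted p = 0.0313 for each). The 6 RBMY genes of a multi-copy germline family had the highest family mean at 0.36 (permutation test against random gene lists, adjusted p = 0.000287). Their difference from AAVS1 (0.04) was not tested. Near-identical copies can share guides, so they are not 6 separate observations. Whether these guides cut a target in these cells was not examined.

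Ribosomal protein genes and their L paralogs went apart in several cases. RPL3 had -1.02 ± 0.17 and RPL3L -0.02 ± 0.28, RPL7 had -1.20 ± 0.34 and RPL7L1 0.03 ± 0.25, and RPS27 had -0.73 ± 0.25 and RPS27L 0.15 ± 0.12 (SE over guides). The RPL3L mean, and so the difference of that pair, includes a guide that was 31.6 times higher in day 0 replicate 1 than in replicate 2. A hypothesis was that parent genes are depleted more than paralogs. Over 8 pairs the mean of parent minus paralog was -0.48 ± 0.55 (SD), with 5 of 8 pairs in that direction, which did not pass an exact sign-flip permutation test (p = 0.0625; the smallest possible is 0.00781). RPL22, RPL36A and RPL39 lay above their paralogs.

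At day 0, 7 guides differed by at least 5 times between technical replicates. The largest was a guide against HNRNPA3 with 49700 normalized units in replicate 1 and 328 in replicate 2, which took 2.59% of all reads in replicate 1 and had 393 and 341 units in the day 7 sets. A guide against TAF2 had 239 and 13658 units.

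Guides of the 100 germline and tissue-restricted genes lay below the AAVS1 guides by -0.23 (95% bootstrap interval -0.29 to -0.17). The tables argue against a different abundance at day 0 as the reason, since the difference was -0.25 (-0.32 to -0.18) after matching day 0 abundance. They also argue against a few strongly depleted guides, since the medians differed by -0.22 (-0.27 to -0.15). Whether the gene guides and the AAVS1 guides differ in cutting or in off-target matches stays open, as guide sequences were not used here, and no biological explanation was tested.

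For the insert found in 6 colonies, abundance of its guide in the bulk cells was argued against by the draws (p = 1e-05, the smallest possible). Reads carried between colonies that shared a PCR index or a library pool were argued against as the whole cause: counting linked colonies once left 3 units, which draws by bulk share exceeded or equalled with p = 0.00228 (one-sided permutation test). For the 6 inserts found in 2 colonies each, such carry-over is a candidate explanation, since 3 of 5 pairs of colonies shared an index (one-sided permutation test, p = 0.0128). In 1 of these 3 pairs, both colonies also held the insert found in 6 colonies, so this count is not separate from it. Over all 19 pairs, including the colonies of the first insert, 5 shared an index (adjusted p = 0.0792, permutation test). Selection of colonies for a shared phenotype stays open and was not tested, because no unselected colonies were used here.

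A further insert, CAGGTCCTACGGGAAGTGA, differed from TAGGTCCTACGGGAAGTGA, which was in 2 colonies, by C1T counted from the 5′ end of the insert.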
